A study of Homo sapiens with 25 samples.

How the data were processed

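Chromatin interactions were measured with PLAC-seq (proximity ligation-assisted ChIP-seq) in 25 libraries of 4 human cancer cell lines. In this assay, chromatin is crosslinked, digested with a restriction enzyme (MboI here, per the labels' protocols) and ligated in place, and the ligation products are enriched with an antibody. The antibody was against H3K4me3, a histone mark of active promoters, so the listed contacts have promoter-marked chromatin at one end or both. The reads were aligned with BWA 0.7.12 to hg38, per the submitters' processing notes. The interaction caller, its expected model and its filters are not given in the sources used here. Per the labels, the libraries of one replicate or clone were merged into 1 list of interactions, which gave 9 lists, with 2 libraries in each HepG2 list and 3 in every other. The list is therefore the replicate in every test.

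Each deposited list holds pairs of 10 kb bins on 1 chromosome, 20 to 1000 kb apart, and 1 value per pair. The value is a score of the authors, between 2 and 7, whose transformation is not given in the deposited files or the labels, and it was used only to rank and filter the interactions within a list. The files give no read counts, expected counts or false discovery rates, so the sequencing depth behind a list is unknown and no counting interval can be given for an interaction. The lists held between 5346 and 113719 interactions. A longer list reaches weaker interactions, and a bin pair missing from a list was not called there, which does not show that the contact was missing from the cells. A score at the maximum of 7 was shared by 109 interactions of K562 replicate 1 and by 15540 of HCT116 clone 34.

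The lists were set to equal length before bins were compared: each kept its 5346 highest-scoring interactions, the length of the shortest list. The 3 HCT116 lists each hold more than 5346 interactions at the maximum score. For the counts per gene bin, the expected count over random orders of the tied interactions was therefore taken, which gives fractions in HCT116. For the overlap of lists, tied interactions were ordered by a rule that was the same in every list, and the mean of 20 such orders was taken, or of 5 where bins could differ by 1. As a consequence of the ties, the HCT116 interactions of the equal-length lists spread over more gene bins. Between 4333 and 5058 gene bins had an expected count above 0 in an HCT116 list, and between 2069 and 2287 in the lists of the other lines. The highest value of a gene bin was between 15.1 and 19.6 in HCT116 and between 29 and 54 in the other lists.

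The gene table used was RefSeq on GRCh38.p14, the build of the lists. It gives gene spans without strand, so transcription start sites, exons, introns and untranslated regions could not be placed. A gene was therefore assigned to the bin of its span boundary that had more interactions over all lists, chosen without regard to the groups, and this bin is called a gene bin. A bin to which several protein-coding genes were assigned is named by all of them. The 19970 protein-coding genes gave 17633 gene bins, of which 12677 had an interaction in a full list. Chromosome Y was left out. Bins with at least 3 interactions in at least 2 equal-length lists were tested, which were 1044, of which 342 hold more than 1 gene.

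The design had been fixed for read counts and false discovery rates, which the files turned out not to hold, so 3 steps were replaced. Counts of interactions that are not read counts, and are partly fractions, were tested with limma 3.58.1 in R 4.3.3 on log2(value + 1), with a trend of the spread on the mean, in place of edgeR. Lists were ranked by the score. Gene bins stood for promoter bins, and a gene boundary in both end bins stood for a promoter at both ends. One fit with a mean per cell line gave, for each line, the difference to the mean of the other 3 lines, and 1 fit with the wild type and the 2 clones apart gave the clones against wild-type HCT116. P-values were two-sided, adjusted with the Benjamini-Hochberg method over the gene bins of a comparison, with a threshold of 0.05. Bins are called higher or lower only where they passed it. A log2 difference against lists at 0 depends on the added 1 and is not a fold. Because each line is set against the mean of the others, a bin with interactions in 1 line only is lower in the comparisons of the other lines by construction. The filter lets in a bin through 1 line alone, so a set of genes with such bins is drawn up in that line and down in the others. At equal length MYB and IKZF1 (K562), SP5, PROX1 and NKD1 (HepG2), TGFB2 and NQO1 (A549), and KITLG and HOXA9 with HOXA10-HOXA9 (HCT116) were such bins. Their calls in either direction are not independent of the filter.

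Of 16 gene lists fixed beforehand (erythroid, haematopoietic, hepatocyte, lung epithelium, intestinal epithelium, epithelial, mesenchymal, NRF2 targets, WNT targets, growth genes, p53 targets, HOX genes, ribosomal proteins, cell cycle, neuronal, and the genes around CDKN2A), 13 had at least 2 tested gene bins. These were tested with fry from limma, two-sided, adjusted over all 65 tests. Camera was run beside it, with a correlation between members estimated from the data. Camera compares the members of a list with the other tested gene bins, and results given with an estimated correlation are from camera. A list that passed by fry only was thus not shown to differ from the other gene bins. The estimated correlations lay between -0.170 (p53 targets) and 0.153 (epithelial genes) in the comparisons of the lines. Fry tests whether the members of a list move one way on balance and does not compare them with other genes. Lists are said to pass by this test. In its test of change in either direction, 50 of the 52 tests of the lines and 2 of the clone tests passed.

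The overlap of lists was measured as the Jaccard index, the number of shared interactions over the number in either list. The mean index of the 6 pairs of lists of 1 line minus that of the other pairs was set against all 1260 partitions of the 9 lists into sets of 3, 2, 2 and 2, in an exact one-sided permutation test whose smallest possible p is 0.000794. The sum of squares between lines of the median distance, and of the percentage of interactions with a gene boundary in both end bins, went through the same partitions in exact two-sided tests.

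The genes named follow a rule set before the data were examined, as were the gene lists, the comparisons and the alternatives listed as planned. Per line, the rule takes the 10 highest and 5 lowest gene bins past the threshold whose lists lie apart from every list of the other lines, and up to 4 members with the lowest adjusted p of each gene list past the threshold. It adds the 10 interactions in all 9 lists with the best mean rank, the genes MYC, CCND1, EGFR, MYB, BCL2L1 and CDK6, and the genes around CDKN2A. Some of the items it takes are not reported here.

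The gene-bin test was checked on simulated data of the 1044 bins, with 50 bins changed at each size. Of the bins raised 8-fold it called between 94 and 98% in the 4 comparisons, of those raised 4-fold between 42 and 70%, of those raised 2-fold between 2 and 12%, and of those lowered to 0.25-fold between 8 and 24%. Of the 844 unchanged bins it called between 0.118 and 0.474%. The simulated values were independent whole counts, without the cutting of lists, the ties and fractions of HCT116 or the spreads near 0 of replicate lists. These shares therefore need not hold for the real lists. The overlap test, in 20 simulated sets of lists at each setting, passed the threshold in a share of 0 without shared interactions and of 1 with them.

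Alternatives tried were the full lists, other filters, merged neighbouring interactions, other ways to assign genes to bins, another added constant, quantile normalization, other tie orders, a replicate block, HCT116 wild type alone, a score of at least 4, interactions over 100 kb, and each list left out in turn. A further one kept the spread of a bin from falling below the counting error of its number of interactions, since replicate lists with equal small numbers give a spread near 0. Overlaps, counts and tables were made with Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9.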

Results

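PLAC-seq contacts of H3K4me3-marked chromatin were collected from 4 cancer cell lines: K562 (a chronic myeloid leukaemia line with erythroid features), HepG2 (a liver cancer line), A549 (a lung adenocarcinoma line) and HCT116 (a colorectal carcinoma line). K562, HepG2 and A549 have 2 replicate lists of interactions each. HCT116 has 3 lists, from wild-type cells and from clone 24 and clone 34, which carry KRAB-dCas9, a Cas9 without nuclease activity fused to a repressor domain and used with guide RNAs to silence regulatory elements. The title of the series states a search for enhancers that promote growth of cancer cells, so contacts of growth genes were among the questions. The K562 lists held 5346 and 6565 interactions, the HepG2 lists 9043 and 11784, and the A549 lists 40358 and 62143. HCT116 had 107612 in the wild type, 93444 in clone 24 and 113719 in clone 34. Sequencing depth is unknown.

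The first question was how far the interactions of a line recur in its own lists and in other lines. Some gene bins were joined to the same partners in all 4 lines. UROD encodes an enzyme of haem synthesis, and its bin (chromosome 1, 45010001 to 45020000) also holds HECTD3 and ZSWIM5. In all 9 full lists this bin was joined to one 290 kb away that starts at 45300001. IRF2BP2 on chromosome 1 was joined to a bin 480 kb away, the calcium sensor gene STIM1 on chromosome 11 to one 220 kb away, and TGIF1, a repressor of TGF-beta signalling, to one 210 kb away. TOB1 (90 kb), ZNF561 (170 kb) and PPCDC with SCAMP5 (180 kb) had such partners too, as did a bin beside the last that held no gene boundary (170 kb). SDR42E2 was joined to POLR3E, an RNA polymerase III subunit gene, over 100 kb, and PCBP1 with ASPRV1 to C2orf42 over 60 kb. These 10 shared the best mean rank with 4 more pairs, which hold BCL2L1, AHCY with DYNLRB1 and ITCH, PIM1, and USP49 with PRICKLE4 and TOMM6.

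On average 92.55 interactions were in all 9 equal-length lists, between 71 and 106 over 20 tie orders. Independent draws from the union of 24473 would give 0.0277, a reference that is too low, since lists of 1 line resemble each other. Pairs of lists of 1 line had a mean Jaccard index of 0.376 and pairs of different lines 0.106 (difference 0.270, exact permutation p = 0.000794, the smallest possible). The index was 0.316 in K562, 0.333 in HepG2, 0.450 in A549 and between 0.361 and 0.406 in HCT116. Between lines it was highest for HepG2 with A549 (mean 0.154) and lowest for K562 with HCT116 (mean 0.0764). In the full lists A549 with HCT116 was highest (mean 0.204) and HepG2 with A549 had 0.106. In the full lists, 310 of the 2916 interactions found in both K562 lists were in no list of another line (10.6%), 731 of 5522 in HepG2 (13.2%), 5308 of 27347 in A549 (19.4%) and 19521 of 44191 in HCT116 (44.2%). These percentages go with list length, since a short list misses interactions that a long one holds. At equal length they were 41.4% in K562, 36.7% in HepG2, 36.1% in A549 and 45.6% in HCT116. The equal-length HCT116 lists leave out many of their interactions at the maximum score, so matches there are missed. Of the interactions of K562 replicate 1, 54.5% were in K562 replicate 2. The longer full lists of A549 replicate 2 and the HCT116 wild type held 61.8% and 64.4% of them.

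**Figure D1:**
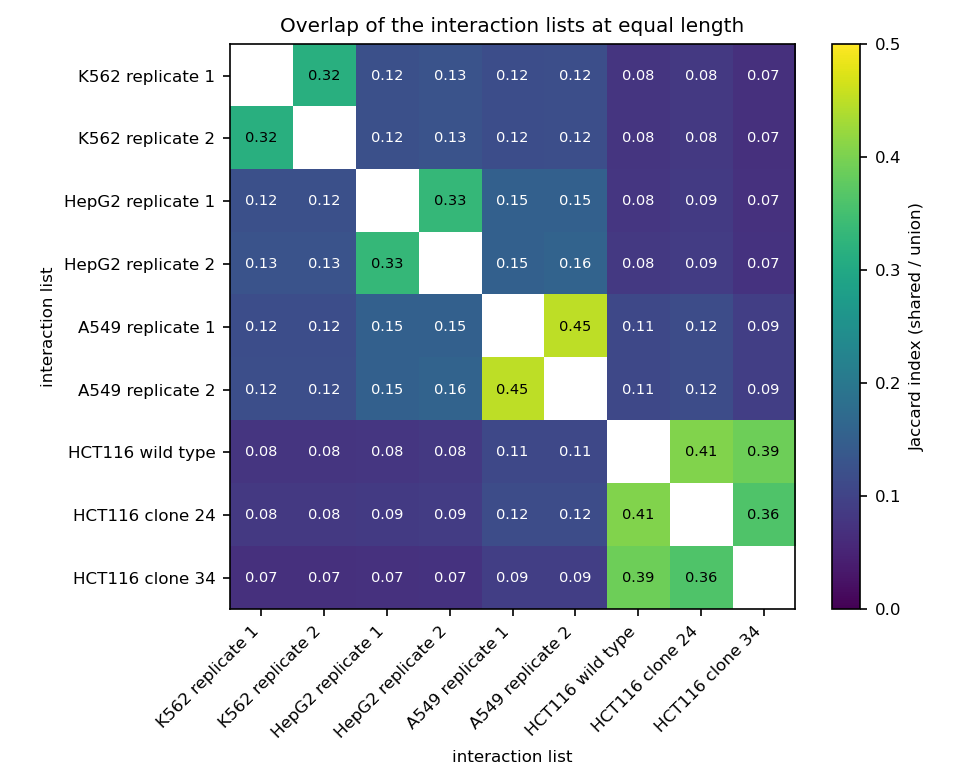
Overlap of each pair of interaction lists at equal length (5346 interactions per list). Both axes give the 9 lists and the colour and number the Jaccard index, shared over total interactions, without a unit. Pairs of 1 line lie between 0.316 and 0.450, and the HepG2 with A549 pairs, with a mean of 0.154, lie above the other pairs of different lines.

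The median distance between the ends differed between lines in the full lists: 170 and 180 kb in K562, 150 kb in both HepG2 lists, 230 and 250 kb in A549, and 300, 270 and 290 kb in the HCT116 wild type, clone 24 and clone 34 (exact permutation p = 0.000794). HCT116 lay 98.3 kb above the mean of the other lists. At equal length the medians were 170 and 180 kb, 140 kb, 190 kb and 150 kb in the same order of lines and again differed between lines (exact permutation p = 0.000794). HCT116 then lay 18.3 kb below the mean of the other lists and above both HepG2 lists. The percentage of interactions with a gene boundary at both ends lay between 15.6 and 19.5% in the full lists and was not shown to differ between lines (exact permutation p = 0.0714). At equal length it differed between lines (exact permutation p = 0.00238), with 15.9 and 15.8% in HepG2 and HCT116 2.51 percentage points above the mean of the other lists. HCT116 alone was not tested against the rest in either measure. The cause of these changes was not tested.

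Next, the number of interactions per gene bin was compared between each line and the other 3, to ask which genes have more promoter-marked contacts in that line. In K562 at equal length, 4 of 6 tested erythroid genes, of 40 in the list, had more interactions than in the other lines. So did all 3 tested haematopoietic genes, of 40 in that list. Neither list passed with an estimated correlation (adjusted p = 0.287 and 0.311), and the erythroid call ended without either K562 list (0.909 and 0.472). MYB, a transcription factor of blood progenitors, had 8 interactions in both K562 lists and 0 in the other 7 at equal length (chromosome 6, 135180001 to 135190000, log2 difference 3.17 ± 0.04 (SE), adjusted p = 3.62e-09). The full HCT116 lists held 5, 4 and 3 at MYB. IKZF1, a transcription factor gene of blood lineages, had 3 in both and 0 in the others (2.00 ± 0.02). NFE2, a regulator of globin genes, had 6 in both and a mean of 0.171 in the others (2.65 ± 0.05). MYB, IKZF1 and NFE2 passed the filter through the K562 lists alone, so their direction was largely set by the filter. Their standard errors are small because both K562 lists held equal numbers, and they leave out the counting error. CCND1, which encodes the cell cycle regulator cyclin D1, had 0 interactions in both K562 lists and a mean of 16.1 in the others (log2 difference -4.06 ± 0.17, adjusted p = 3.52e-06).

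Of the 1044 gene bins, 271 were higher and 389 lower in K562. The higher bins fell to 125 without K562 replicate 1 and 108 without replicate 2, and with merged interactions 70 were higher and 274 lower. The K562 lists lay apart from every other list in 306 bins (29.3%), where interchangeable lists would give 5.56%. This reference is too low, since lists of 1 line resemble each other and the filter lets in bins through 1 line alone. The highest was CCDC71L (chromosome 7, 106650001 to 106660000), with 14.5 ± 2.1 interactions (SD, n = 2) and 0 in the other lists (log2 difference 3.95 ± 0.09, adjusted p = 1.37e-07). Next came the kinase gene BMP2K (3.75 ± 0.06), the histone genes H2AC11, H2BC11, H2BC12 and H4C9 in 1 bin of the histone cluster on chromosome 6 (23.5 ± 2.1 interactions, 3.75 ± 0.19), and PTGER3, a prostaglandin receptor gene (3.70 ± 0.07). STXBP5 (3.58 ± 0.34), the transcriptional co-regulator gene CITED2 (28.5 ± 2.1 interactions, 3.30 ± 0.48), CLTCL1 with SLC25A1 (3.28 ± 0.25), H2AC12 (3.17 ± 0.35) and GLI1 with INHBC and INHBE (3.15 ± 0.24) followed. The lowest beside CCND1 were the Notch ligand gene JAG1 (-4.11 ± 0.20), ZNF703 (-3.99 ± 0.28), MARCKS (-3.41 ± 0.24) and NR2F1 (-3.13 ± 0.22), all with 0 interactions in both K562 lists.

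Of the 6 tested erythroid genes, 4 were higher in K562, with UROD as the fourth (1.06 ± 0.38), and none was lower (fry adjusted p = 1.62e-06, adjusted p = 0.287 with an estimated correlation). The UROD call ended without any 1 list other than HepG2 replicate 1 and A549 replicate 2 (adjusted p between 0.0506 and 0.233). In the full lists the UROD bin had 6 and 10 interactions in K562. The HepG2 lists held 10 and 8, and the longer A549 and HCT116 lists held more, 18 and 22 in A549 and 33, 30 and 28 in HCT116. All 3 haematopoietic genes were higher, HHEX (2.36 ± 0.17), the kinase gene PIM1 (1.81 ± 0.15) and MEIS1 (0.99 ± 0.22), with fry adjusted p = 3.43e-05 and adjusted p = 0.311 with an estimated correlation. Most erythroid markers could not be tested: HBG1, HBG2, HBE1 and HBZ had 0 interactions in all full lists, and TAL1 had 1, in K562 replicate 1. Lists of other tissues went down on balance, in part by construction, since members such as PROX1 and SP5 had interactions in HepG2 only at equal length. Of all 1044 bins, 389 were lower in K562 and 271 higher. Of 16 WNT targets 11 were lower, among them NKD1 (-0.94 ± 0.03) and LGR4 (-1.30 ± 0.06), while MYC and GLUL were higher (fry adjusted p = 9.30e-06, adjusted p = 0.287 with an estimated correlation). All 4 lung epithelium genes were lower, such as GPRC5A (-1.44 ± 0.12), and 4 of 5 hepatocyte genes, such as PROX1 (-1.39 ± 0.07) and APOA1 with APOC3 (-1.03 ± 0.12). The fry adjusted p were 3.65e-05 and 4.91e-05, and with an estimated correlation the adjusted p = 0.318 and 0.358. The call of CAV1, a lung list member, ended without K562 replicate 2 (-0.48 in place of -0.77, adjusted p = 0.0889). FOXA1 (-2.29 ± 0.23) and FOXA2 (-1.43 ± 0.16), pioneer factors of endoderm, are in both lists.

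Epithelial genes were lower in 5 of 6 cases, ELF3 (-2.63 ± 0.20) and KRT7 (-0.72 ± 0.07) among them (fry adjusted p = 2.98e-04, adjusted p = 0.425 with an estimated correlation). Of 7 NRF2 targets, genes of the oxidative stress response, 5 were lower, such as UGDH (-2.31 ± 0.20), with a median of -0.85, and the ferritin gene FTH1, in 1 bin with BEST1, was higher (0.93 ± 0.14; fry adjusted p = 5.80e-05, adjusted p = 0.544 with an estimated correlation). The NRF2 median was -0.26 over 4 genes without A549 replicate 2, and 0.02 with full lists, where that of all bins was 0.49. Of 8 mesenchymal genes 5 were lower, such as TGFB2 (-1.68 ± 0.10) and ZEB1 (-1.45 ± 0.20), and VIM was higher (2.82 ± 0.24; fry adjusted p = 2.15e-04, adjusted p = 0.498 with an estimated correlation). Of 16 growth genes 11 were lower, including CDK6 (-1.62 ± 0.11) and EGFR (-1.62 ± 0.14), and 4 higher, including MYB and MYC (fry adjusted p = 2.67e-04, adjusted p = 0.425 with an estimated correlation). This call ended with no filter (median -0.17, adjusted p = 0.381), with at least 5 interactions (0.119) and with other tie orders (0.600). Of 9 HOX bins 5 were lower, such as HOXA5 with HOXA6 (-1.65 ± 0.15), and HOXB9 was higher (1.33 ± 0.14; fry adjusted p = 0.00127, adjusted p = 0.884 with an estimated correlation). The HOX call ended with full lists (median -0.58, adjusted p = 0.570). Cell cycle genes (1 higher, 3 lower of 9, fry adjusted p = 0.0764), p53 targets (2 higher, 1 lower of 4, 0.0777) and ribosomal protein genes (1 higher of 6, 0.865) did not pass. For p53 targets the test pointed down and the median (0.32) and mean (0.11) up, and for ribosomal protein genes the test and median (0.04) pointed up and the mean (-0.10) down. Adjusted over the list alone, the counts were the same, except for 12 lower WNT targets and no higher ribosomal protein gene. With the spread kept at the counting error, 115 bins were higher and 66 lower in K562. Over all comparisons, 69 of the 184 gene bins past the threshold that the naming rule takes kept their call. With full lists scaled to their lengths, 350 of 692 bins were higher and 230 lower, and the mesenchymal median changed from -0.98 to 0.04 and that of all bins from -0.27 to 0.49. Without K562 replicate 1 the erythroid median was 0.17 over 2 genes (adjusted p = 0.909) and without replicate 2 it was 0.81 over 3 genes (adjusted p = 0.472), since the filter then left out genes with interactions in K562 only. The mesenchymal call ended without A549 replicate 1 (median -0.54, adjusted p = 0.732) and without A549 replicate 2 (-0.34, adjusted p = 0.217).

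**Figure D2:**
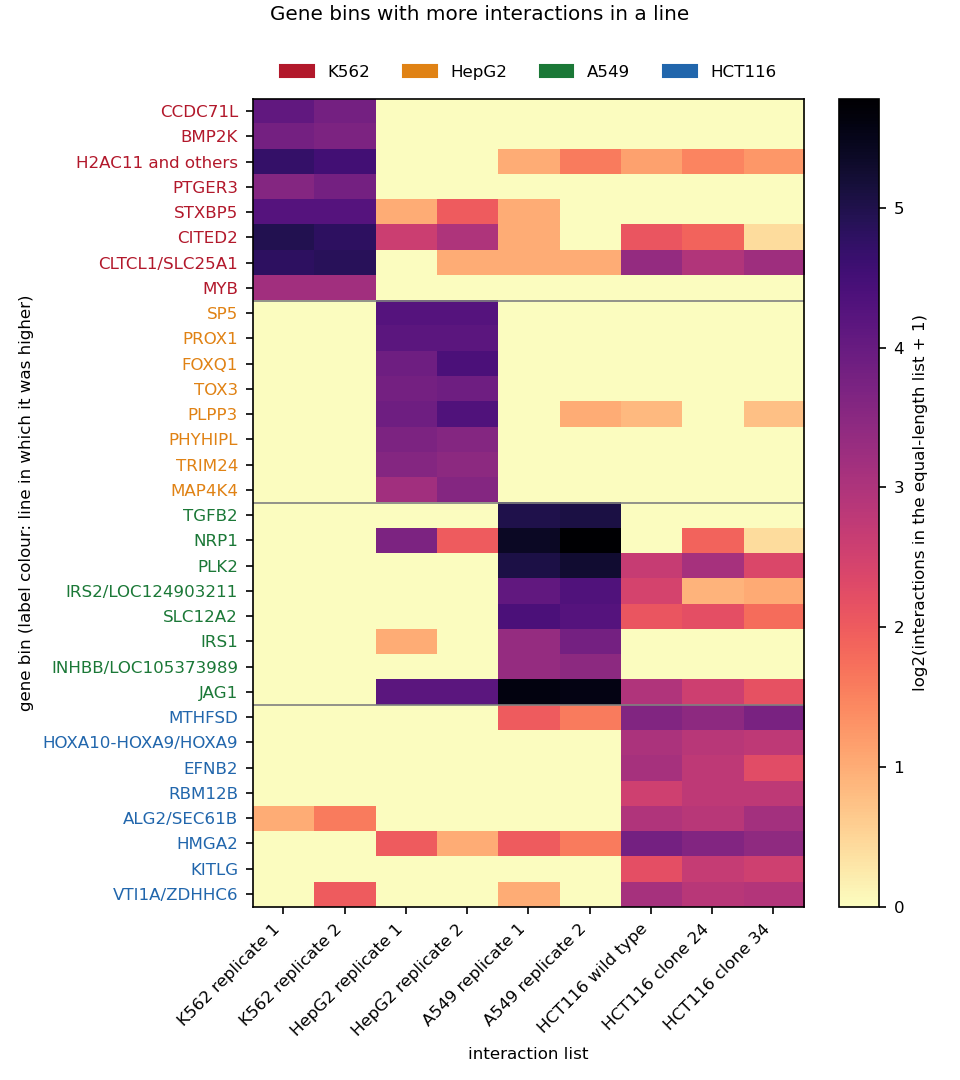
Of the highest gene bins by the rule for named genes, 8 per line, with the line given by the colour of the label. Columns are the 9 lists and the colour is log2 of the number of interactions in the equal-length list plus 1. MYB has 8 interactions in both K562 lists and 0 in the others, and TGFB2 has 31 and 32.7 in A549 and 0 in the others.

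In HepG2 at equal length, all 5 tested hepatocyte genes, of 56 in the list, and 11 of 16 WNT targets had more interactions than in the other lines. Neither list passed with an estimated correlation (adjusted p = 0.287 for both). SP5, a transcription factor gene induced by WNT, had 18 interactions in both HepG2 lists and 0 in the other 7 (chromosome 2, 170710001 to 170720000; log2 difference 4.25 ± 0.07, adjusted p = 2.28e-08). PROX1, a transcription factor of liver and lymphatic development, had 17 in both and 0 in the others (chromosome 1, 213980001 to 213990000; 4.17 ± 0.07, adjusted p = 2.12e-08). NKD1, a feedback inhibitor of WNT signalling, had 6 in both and 0 in the others (2.81 ± 0.03). SP5, PROX1 and NKD1 passed the filter through the HepG2 lists alone, so their direction was largely set by the filter. Their standard errors are small because both HepG2 lists held equal numbers, and they leave out the counting error. The HOXB genes were low: HOXB7 with HOXB8 had 0 in HepG2 and a mean of 14.8 in the others (-3.38 ± 0.16), and HOXB9 had 0 (-3.20 ± 0.14).

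In all, 283 gene bins were higher and 308 lower in HepG2. The higher bins fell to 151 without HepG2 replicate 1 and 138 without replicate 2, and with merged interactions 124 were higher and 157 lower. Its lists lay apart from all others in 252 of the 1044 bins, where interchangeable lists would give 5.56%, a reference that is too low, as in K562. FOXQ1 (17 ± 4.24 interactions, SD, n = 2; log2 difference 4.15 ± 0.13), TOX3 (3.86 ± 0.06), PLPP3 (3.77 ± 0.34), PHYHIPL (3.64 ± 0.06) and the co-regulator gene TRIM24 (3.52 ± 0.05) followed PROX1. MAP4K4 (3.38 ± 0.10), SEPTIN10 with SOWAHC (3.25 ± 0.05) and FRY (3.17 ± 0.04) completed the highest. Beside the HOXB bins, the lowest were YWHAZ, a 14-3-3 protein gene (-2.73 ± 0.26), the Mediator subunit gene MED13L (-2.73 ± 0.46, and -1.73 without HepG2 replicate 1) and the caveolin gene CAV1 (-2.49 ± 0.19).

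All 5 tested hepatocyte genes were higher in HepG2 (fry adjusted p = 3.23e-06, adjusted p = 0.287 with an estimated correlation). Among them were FOXA1 (12 ± 4.24 interactions, 2.59 ± 0.23), FOXA2 (16.5 ± 0.7 interactions, 2.35 ± 0.16) and the apolipoprotein genes APOA1 and APOC3 in 1 bin (1.85 ± 0.12). In the full lists, which differ in length, this bin had 5 and 3 in HepG2, 3 and 3 in A549 and 3, 5 and 5 in HCT116. The APOA2 bin had 7 and 7 in HepG2 and 6, 6 and 9 in HCT116. ALB, the albumin gene, had 3 and 2 interactions in the full HepG2 lists and 0 in the others, too few for the filter, as did APOB with 3 in both. Of 16 WNT targets, 11 were higher, including SP5, PROX1, NKD1 and the receptor gene LGR4 (0.81 ± 0.06), and EPHB3 and MYC were lower (fry adjusted p = 1.65e-06, adjusted p = 0.287 with an estimated correlation). PROX1 is in both of these lists. Of 9 HOX bins 8 were lower, with HOXC9 (-1.40 ± 0.12) and HOXA9 with HOXA10-HOXA9 (-0.96 ± 0.10) after the HOXB genes, and HOXA5 with HOXA6 was higher (fry adjusted p = 3.01e-05, adjusted p = 0.318 with an estimated correlation). Of 8 mesenchymal genes 5 were lower, including TGFB2 (-1.68 ± 0.10), ZEB1 (-1.45 ± 0.20) and VIM (-1.16 ± 0.24; fry adjusted p = 3.50e-05, adjusted p = 0.318 with an estimated correlation). The erythroid genes IKZF1 (-0.67 ± 0.02), MYB (-1.06 ± 0.04) and NFE2 (-1.10 ± 0.05) were lower and ZFPM1 was higher (0.80 ± 0.28; fry adjusted p = 3.50e-05, adjusted p = 0.498 with an estimated correlation). IKZF1 and MYB had interactions in K562 only at equal length, so their lower values, and with them part of this shift, are by construction. ZFPM1 was at 0.40 without HepG2 replicate 2 (adjusted p = 0.346) and at 1.20 without replicate 1. Its call also ended without K562 replicate 2, A549 replicate 1 or any 1 HCT116 list (adjusted p between 0.0714 and 0.0804). Of 4 p53 targets PLK2 was lower (-2.62 ± 0.20), and SESN1 with CEP57L1 (-0.64), POLH with XPO5 (0.67) and GDF15 (-0.14) did not pass (fry adjusted p = 8.83e-04, adjusted p = 0.812 with an estimated correlation).

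Ribosomal protein genes were lower in 4 of 6 cases in HepG2: RPL30 (-0.94 ± 0.11), RPL28 with TMEM238 (-1.97 ± 0.25), RPL35 with ARPC5L (-1.14 ± 0.26) and RPL7 with RDH10 (-1.62 ± 0.42; fry adjusted p = 0.00184, adjusted p = 0.498 with an estimated correlation), while with full lists the median of the list was 0.18, below the 0.33 of all bins. The RPL35 call ended without HepG2 replicate 2 (-0.93, adjusted p = 0.0788) and the RPL7 call without replicate 1 (-0.83, 0.0860). Of 16 growth genes 6 were lower, such as EGFR (-1.62 ± 0.14), and 5 higher, such as FOXA1 and CCND1 (1.21 ± 0.17; fry adjusted p = 0.00216, adjusted p = 0.968 with an estimated correlation), and with full lists the median changed from -0.29 to 0.37, near the 0.33 of all bins. Of 7 NRF2 targets NQO1 (-0.85 ± 0.11), TXNRD1 (-0.87 ± 0.12) and AKR1B10 (-0.76 ± 0.13) were lower, and UGDH (1.91 ± 0.20) and GCLC higher (fry adjusted p = 0.0291, adjusted p = 0.968 with an estimated correlation), with a median of -0.61 and, with full lists, of 1.44 over 3 genes. Epithelial genes (2 higher, 2 lower of 6, 0.317), haematopoietic genes (1 higher, 1 lower of 3, 0.272), lung epithelium genes (2 higher, 2 lower of 4, 0.854) and cell cycle genes (1 higher, 2 lower of 9, 0.626) did not pass by their fry adjusted p. The signs of median, mean and test differed for the epithelial list (median -0.02, mean 0.10, test down), the haematopoietic list (median 0.01, mean -0.22, test down) and the lung list (median 0.46, mean 0.25, test down). Adjusted over the list alone, the counts were the same except for 3 lower WNT targets, 7 lower growth genes and 1 lower cell cycle gene. With the spread kept at the counting error, 98 bins were higher and 15 lower in HepG2, and with full lists 315 of 692 bins were higher and 201 lower. Without some lists the medians changed sign: the erythroid median was 0.78 without K562 replicate 1 and 0.70 without K562 replicate 2, and the NRF2 median was 0.65 without A549 replicate 1 and 0.39 without A549 replicate 2. The growth gene median was 0.15 without HepG2 replicate 1, 0.14 without A549 replicate 1, 0.043 without A549 replicate 2 and 0.11 without clone 24 or 34. The NRF2 call also ended without either K562 list, either HepG2 list, the HCT116 wild type or clone 24 (adjusted p between 0.0514 and 0.200), and the growth gene call without either K562 list, either HepG2 list or clone 24 (0.0569 to 0.472).

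In A549, 7 of 8 mesenchymal genes had more interactions than in the other lines, and 4 of 7 NRF2 targets did at equal length, though the NRF2 median was -0.61 with full lists, where that of all bins was -0.36. Neither list passed with an estimated correlation (adjusted p = 0.287 for both). TGFB2, which encodes a TGF-beta ligand, had 31.9 ± 1.2 interactions (SD, n = 2) in A549 and 0 in the other 7 lists (chromosome 1, 218340001 to 218350000; log2 difference 5.04 ± 0.10, adjusted p = 1.42e-07). IRS1 (3.40 ± 0.25) and IRS2/LOC124903211 (3.72 ± 0.40), which encode adaptors of the insulin receptor, were higher as well. NQO1, a quinone reductase gene and NRF2 target, had 5 ± 1.41 interactions in A549 and 0 in the others (chromosome 16, 69720001 to 69730000; 2.56 ± 0.11, adjusted p = 4.30e-06). The glutamine synthetase gene GLUL, in 1 bin with TEDDM1, was lower (0.5 ± 0.707 interactions against a mean of 12, -3.06 ± 0.29).

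In A549, 292 gene bins were higher and 267 lower. Its lists lay apart from all others in 241 bins (23.1%), where interchangeable lists would give 5.56%, a reference that is too low, as in K562. Among the highest beside TGFB2 were the semaphorin co-receptor gene NRP1 (47.5 ± 9.19 interactions, 4.38 ± 0.59) and the kinase gene PLK2 (34.5 ± 3.54 interactions, 4.25 ± 0.20). The ion cotransporter gene SLC12A2 (3.65 ± 0.15), INHBB/LOC105373989, an activin subunit gene (3.39 ± 0.05), JAG1 (47.4 ± 0.9 interactions, 3.35 ± 0.20) and CSGALNACT1 (3.25 ± 0.05) were among them too, beside the insulin receptor adaptors. The other lowest bins were JARID2, a Polycomb partner gene (-2.42 ± 0.13), ABHD16B with TPD52L2 (-2.23 ± 0.25), ANKRD17 (-2.19 ± 0.22) and the translation factor gene EIF2S2 (-2.15 ± 0.24).

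Of 8 mesenchymal genes in A549, 7 were higher, including TGFB2, CAV1 (13 ± 1.41 interactions, 2.58 ± 0.19), the receptor kinase gene AXL with HNRNPUL1 (1.80 ± 0.28) and CCN1 (1.66 ± 0.26), and VIM did not pass (-0.50; fry adjusted p = 3.42e-06, adjusted p = 0.287 with an estimated correlation). Of 7 NRF2 targets, NQO1, AKR1B10 (2.29 ± 0.13), TXNRD1 (1.80 ± 0.12) and UGDH (0.96 ± 0.20, and -0.11 with full lists) were higher and none was lower (fry adjusted p = 4.92e-06, adjusted p = 0.287 with an estimated correlation), but with full lists the median over the 3 genes left was -0.61, below the -0.36 of all bins. The UGDH call ended without A549 replicate 2 (adjusted p = 0.0686). All 4 lung epithelium genes were higher, with GPRC5A (2.30 ± 0.12), FOXA2 (15.5 ± 0.7 interactions, 2.24 ± 0.16) and FOXA1 (1.58 ± 0.23) beside CAV1 (fry adjusted p = 1.02e-05, adjusted p = 0.287 with an estimated correlation). Of these, CAV1 is also a mesenchymal gene and the FOXA genes are also hepatocyte genes. In the full lists CAV1 had 30 and 30 in A549 and 35, 29 and 33 in the longer HCT116 lists, and GPRC5A had 9 and 9, and 7, 8 and 10. FOXA1 had 21 and 33 in A549 and 7, 3 and 10 in HCT116, and FOXA2 had 28 and 29, and 1, 0 and 0. The lung marker NKX2-1 had 1 interaction in the full HCT116 wild-type list and 0 in the others, and SFTPA1, a surfactant gene, had 0 in all. Of 16 growth genes 10 were higher, such as CDK6 (1.60 ± 0.11), CCND1 (27 ± 2.83 interactions, 2.34 ± 0.17) and IRS1, and 2 lower, such as MYB (-1.06 ± 0.04; fry adjusted p = 3.50e-05, adjusted p = 0.318 with an estimated correlation). Of 9 HOX bins 7 were higher, such as HOXB7 with HOXB8 (26.5 ± 0.7 interactions, 2.99 ± 0.16), HOXA5 with HOXA6 (2.07 ± 0.15) and HOXC9 (1.48 ± 0.12), and HOXA9 with HOXA10-HOXA9 was lower (-0.96 ± 0.10; fry adjusted p = 9.01e-05, adjusted p = 0.382 with an estimated correlation).

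The keratin genes KRT7 (2.16 ± 0.07) and KRT18 (1.71 ± 0.32), the integrin gene ITGA3 (2.03 ± 0.16) and ELF3 (2.06 ± 0.20) were higher in A549, and the epithelial genes ESRP2 and DSP were lower (fry adjusted p = 1.50e-04, adjusted p = 0.570 with an estimated correlation). Of 4 p53 targets PLK2 was higher and SESN1 with CEP57L1 lower (-1.31 ± 0.34), the latter only with both A549 lists (adjusted p = 0.0924 without replicate 1 and 0.0881 without replicate 2). The p53 test (up, fry adjusted p = 5.76e-04, adjusted p = 0.968 with an estimated correlation) and the mean (0.60) differed in sign from the median (-0.26). That median was 1.76 over 2 genes without K562 replicate 1, -0.040 without HepG2 replicate 1, -0.11 without A549 replicate 1 and -0.41 without A549 replicate 2. Of 3 haematopoietic genes MEIS1 was higher (4.5 ± 2.12 interactions against a mean of 1.71; fry adjusted p = 0.0219, adjusted p = 0.929 with an estimated correlation), with a median of 0.36 and, with full lists, of -0.07, above the -0.36 of all bins. The median of the list was 0.069 without A549 replicate 1 and 0.65 without replicate 2. The log2 difference of MEIS1 was 0.70 without A549 replicate 1. The erythroid genes IKZF1 (-0.67 ± 0.02), MYB and NFE2 (-1.10 ± 0.05) were lower (fry adjusted p = 2.87e-05, adjusted p = 0.287 with an estimated correlation). IKZF1 and MYB had interactions in K562 only at equal length, so their lower values, and with them part of this shift, are by construction. Of 5 hepatocyte genes FOXA1 and FOXA2 were higher and PROX1 (-1.39 ± 0.07) and APOA1 with APOC3 (-1.03 ± 0.12) lower. In the full lists APOA1 with APOC3 had 3 and 3 in A549 and 5 and 3 in the shorter HepG2 lists. The hepatocyte test (down, fry adjusted p = 0.0392, adjusted p = 0.968 with an estimated correlation) and median (-0.23) differed in sign from the mean (0.23), and the median was 1.69 without HepG2 replicate 1 and 1.47 without HepG2 replicate 2. Without K562 replicate 1 the hepatocyte test pointed up and passed (median -0.014, adjusted p = 0.0290), and it also pointed up without K562 replicate 2 (-0.45). With a replicate block the call ended (adjusted p = 0.0696). Ribosomal protein genes (1 higher, 1 lower of 6, 0.444), cell cycle genes (1 higher, 2 lower of 9, 0.452) and WNT targets (7 higher, 5 lower of 16, 0.920, test down with a median of 0.19) did not pass by their fry adjusted p. Adjusted over the list alone, the counts were the same except for 4 lower erythroid genes. With the spread kept at the counting error 93 bins were higher and 4 lower in A549, and the number of calls fell from 559 to 321 without A549 replicate 1 and to 315 without replicate 2, of which 123 and 121 were higher. With full lists 142 of 692 bins were higher and 289 lower. The epithelial call ended without A549 replicate 1 (adjusted p = 0.898) or replicate 2 (0.231), the erythroid call without K562 replicate 2 (0.101), the haematopoietic call without K562 replicate 2 (0.0851) or HepG2 replicate 1 (0.0522), and the hepatocyte call without K562 replicate 2 (0.251) or A549 replicate 1 (0.0899) or 2 (0.121).

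In HCT116, over its 3 lists, a HOXA bin, HMGA2 and KITLG had more interactions, and the endodermal factors FOXA1 and FOXA2 had fewer. HOXA9 with HOXA10-HOXA9 had 6.46 ± 0.73 interactions (SD, n = 3) in HCT116 and 0 in the other 6 lists (chromosome 7, 27160001 to 27170000; log2 difference 2.89 ± 0.08, adjusted p = 6.45e-07). HMGA2, a chromatin architectural gene, had 11.2 ± 1.65 and a mean of 1.5 in the others (2.51 ± 0.24), and KITLG, the ligand gene of the KIT receptor, 4.6 ± 0.882 and 0 (2.47 ± 0.10). FOXA2 had 0 in all 3 HCT116 lists and a mean of 11.2 in the others (chromosome 20, 22580001 to 22590000; -3.15 ± 0.14, adjusted p = 5.23e-06). Values of HCT116 are flatter than those of the other lines because of the ties at the maximum score. With the spread kept at the counting error, none of the HCT116 calls remained.

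In HCT116, 248 gene bins were higher and 298 lower, and with merged interactions 295 were higher and 124 lower. The higher bins fell to between 164 and 169 without 1 of the HCT116 lists. The HCT116 lists lay apart from all others in 179 bins (17.1%), where interchangeable lists would give 2.38%, a reference that is too low, as in K562. MTHFSD (3.00 ± 0.14), the ephrin gene EFNB2 (2.71 ± 0.18), RBM12B (2.70 ± 0.07) and ALG2 with the translocon gene SEC61B (2.57 ± 0.17) were among the highest, followed by VTI1A with ZDHHC6 (2.46 ± 0.45), PGLS (2.42 ± 0.07) and PHB2 with PTPN6 (2.39 ± 0.22). The lowest after FOXA2 were HNRNPLL (-2.72 ± 0.13), IRF2BP2 (-2.70 ± 0.21), BAMBI, a TGF-beta pseudoreceptor gene (-2.29 ± 0.44), and PIM1 (-2.27 ± 0.13).

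Of 9 HOX bins in HCT116, 4 were higher, with HOXB7 and HOXB8 (15.8 ± 1.21 interactions, 2.05 ± 0.14) and HOXB9 (1.47 ± 0.12) after HOXA9, and HOXA5 with HOXA6 was lower (-1.65 ± 0.13; fry adjusted p = 7.73e-05, adjusted p = 0.382 with an estimated correlation). Of 6 ribosomal protein genes 4 were higher, RPL30 (1.06 ± 0.10, and -0.58 with full lists), RPL28 (1.25 ± 0.22), RPL35 (1.16 ± 0.23) and RPLP0 (1.57 ± 0.37; fry adjusted p = 4.02e-04, adjusted p = 0.318 with an estimated correlation), but with full lists the median over 3 genes was -0.58, near the -0.56 of all bins. All 3 haematopoietic genes were lower, with MEIS1 (-2.10 ± 0.19) and HHEX (-1.36 ± 0.15) beside PIM1 (fry adjusted p = 1.67e-05, adjusted p = 0.295 with an estimated correlation). Of 5 hepatocyte genes, FOXA2, FOXA1 (-1.88 ± 0.20) and PROX1 (-1.39 ± 0.06) were lower, and APOA2 with NR1I3 and TOMM40L did not pass (-0.73; fry adjusted p = 2.52e-05, adjusted p = 0.358 with an estimated correlation). Of 16 WNT targets 7 were lower, such as NKD1 (-0.94 ± 0.02), LGR4 (-1.30 ± 0.05) and SP5 (-1.42 ± 0.06), and 5 higher, such as EPHB3 and TCF7L2 (fry adjusted p = 3.76e-05, adjusted p = 0.498 with an estimated correlation). The erythroid genes IKZF1 (-0.67 ± 0.01), MYB (-1.06 ± 0.03) and NFE2 (-0.45 ± 0.05) were lower (fry adjusted p = 1.91e-04, adjusted p = 0.425 with an estimated correlation). IKZF1 and MYB had interactions in K562 only at equal length, so their lower values, and with them part of this shift, are by construction. The full HCT116 lists held 5, 4 and 3 interactions at MYB.

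Of 7 NRF2 targets in HCT116, FTH1 with BEST1 (-1.22 ± 0.13), NQO1 (-0.85 ± 0.10), AKR1B10 (-0.76 ± 0.11) and UGDH (-0.55 ± 0.18, and 0.00 with full lists) were lower (fry adjusted p = 1.91e-04, adjusted p = 0.350 with an estimated correlation). The UGDH call ended without any 1 list other than A549 replicate 1 and the wild type (adjusted p between 0.0549 and 0.0846, and a log2 difference of -0.36 without clone 24). Of 4 lung epithelium genes the FOXA genes were lower and GPRC5A (0.57 ± 0.11) and CAV1 (0.69 ± 0.17) higher (fry adjusted p = 2.98e-04, adjusted p = 0.968 with an estimated correlation). The CAV1 call ended without the wild type (adjusted p = 0.0568) or clone 24 (0.0636), and the call of the list ended with the wild type as the only HCT116 list (0.216). Of 8 mesenchymal genes TGFB2 (-1.68 ± 0.09), TPM1 (-1.35 ± 0.22), VIM (-1.16 ± 0.21) and AXL were lower and ZEB1 (1.76 ± 0.18) and CAV1 higher (fry adjusted p = 0.00103, adjusted p = 0.944 with an estimated correlation). Growth genes (5 higher, 6 lower of 16, 0.259), cell cycle genes (3 higher, 1 lower of 9, 0.0768), epithelial genes (3 higher, 2 lower of 6, 0.854) and p53 targets (1 higher, 1 lower of 4, 0.452, test up with a median of -0.19) did not pass by their fry adjusted p. Intestinal genes could not be tested as a list, since only EPHB3 passed the filter (1.31 in HCT116 and 1.34 in A549). In the full lists CDX2, a transcription factor of intestinal epithelium, had 2, 3 and 2 interactions in HCT116 and 0 in the other lines, and KRT20 had 0 in all. Of the neuronal genes only GAD1 passed the filter, which was higher in K562 (2.27) and did not pass in HCT116 (-0.39). Adjusted over the list alone, the counts were the same except for 4 lower hepatocyte genes, 9 lower WNT targets and 7 lower growth genes. With the spread kept at the counting error 0 bins of HCT116 passed in limma, and 273 had an unadjusted p under 0.05. With full lists 60 of 692 bins were higher and 414 lower, and with the wild type as the only HCT116 list 58 were higher and 135 lower. Without K562 replicate 1 or 2 the erythroid call ended (median -0.10 and 0.23). Without HepG2 replicate 1 or 2 the WNT call ended (0.15 and 0.37), and without A549 replicate 1 or 2 the mesenchymal test pointed up (median -0.78 and -0.70).

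The clones that carry KRAB-dCas9 were compared with wild-type HCT116, to ask whether the contacts of promoter-marked chromatin differ in the lines used for silencing. The Jaccard index was 0.406 for the wild type with clone 24, 0.389 for the wild type with clone 34 and 0.361 for clone 24 with clone 34, where replicates of the other lines had between 0.316 and 0.450. With bins allowed to differ by 1 the HCT116 pairs had between 0.457 and 0.499, below the 0.519 to 0.635 of the other replicates. In full lists they then had between 0.596 and 0.601, above the 0.518 to 0.564 of the others. PIP4K2A, a phosphoinositide kinase gene on chromosome 10, had a mean of 3.11 in the clones and 1.21 in the wild type (log2 difference 0.89 ± 0.03, adjusted p = 4.51e-04). EFR3A on chromosome 8 had 3.51 and 1.61 (0.79 ± 0.08, adjusted p = 0.0421). MARCHF10 on chromosome 17 had 0 in both clones and 0.404 in the wild type (-0.49 ± 0.02, adjusted p = 0.00114), which is the expected count of 1 interaction at the maximum score.

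These were the only bins of 1044 past the threshold between the clones and the wild type, and 50 had an unadjusted p under 0.05. The wild type has 1 list, which was assumed to vary like the other lists, so the standard errors hold no spread of the wild type and the 3 calls do not show a difference between the groups. A difference of the clones cannot be told from a difference of culture. With the spread kept at the counting error the number of calls was 0, and all 3 genes had an adjusted p of 1. The EFR3A call ended without either K562 or either HepG2 list (adjusted p between 0.128 and 0.236), and the MARCHF10 call without HepG2 replicate 1 (0.0507). None of the 13 gene lists passed in the test of a shift one way: the lowest fry adjusted p were 0.0829 for WNT targets, 0.0889 for growth genes and 0.0944 for HOX genes, and the highest was 0.996 for erythroid genes. Epithelial genes had 0.191, hepatocyte genes 0.449, cell cycle genes 0.786, haematopoietic and other lists 0.854 or more. In the fry test of change in either direction growth genes (adjusted p = 1.40e-06) and WNT targets (0.00200) passed, with the same limit of 1 wild-type list. Adjusted over the list alone, 1 growth gene was lower and no other member passed.

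At the growth gene loci, MYC had interactions in all 9 full lists, 52 and 55 in K562, 34 in both HepG2 lists, 89 and 104 in A549 and 91, 80 and 85 in the HCT116 wild type, clone 24 and clone 34 (MYC bin at chromosome 8, 127730001 to 127740000). The side of the partners, counted after the values were seen, differed between lines. All partners in K562 lay at higher coordinates, up to 770 kb away. In HepG2, 4 of 34 and 6 of 34 lay at lower coordinates, in A549 33 and 42, and in HCT116 41, 50 and 46. In 5 partner bins between 128160001 and 128330000 an interaction was listed in all 9 lists, and 5 bins between 127080001 and 127350000 were partners in all HCT116 lists and in no other line. At equal length MYC was higher in K562 (52.5 ± 0.707 interactions, 1.50 ± 0.16), and lower in HepG2 (15.5 ± 2.12, -0.77 ± 0.16) and HCT116 (12.1 ± 2.45, -1.22 ± 0.14). The shortest list, K562 replicate 1, was not cut, and the HCT116 values are expected counts over tied interactions. At the maximum score MYC had 1 and 2 interactions in K562, 0 and 1 in HepG2, 23 and 29 in A549 and 37, 24 and 31 in HCT116. The K562 direction held with full lists scaled to their lengths, where the median of all bins was 0.49, and not with merged neighbouring interactions (-0.36). In HepG2 the difference was 0.37 with full lists, near the 0.33 of all bins. In A549 it was 0.49 ± 0.16 at equal length and -0.59 with full lists, and the A549 call ended without any 1 of 7 lists, whose values lay between 0.44 and 0.51.

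**Figure D3:**
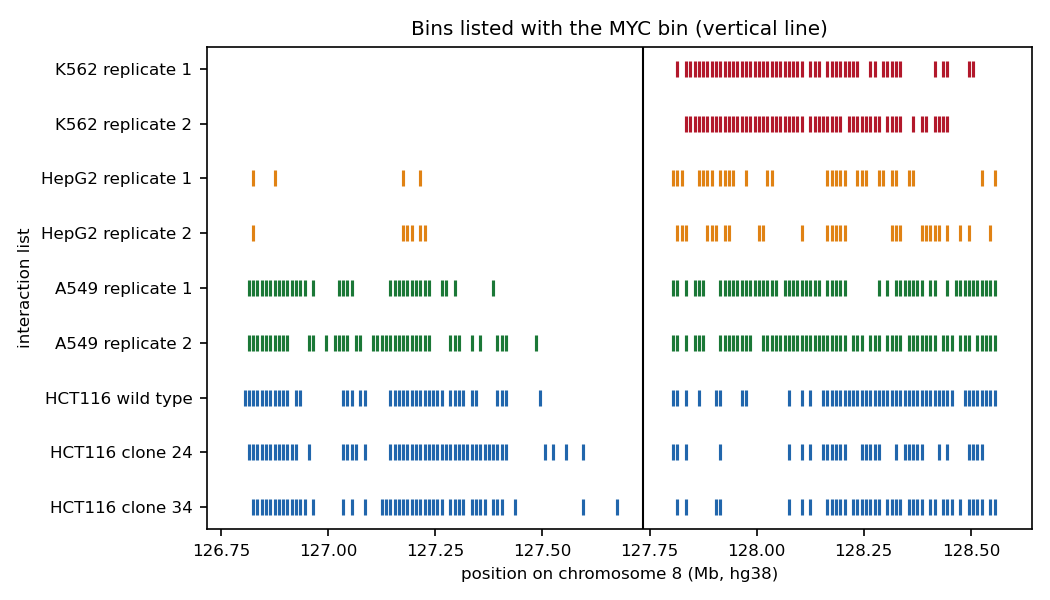
Bins listed with the MYC bin in the 9 full lists. The horizontal axis is the position on chromosome 8 in Mb (hg38), each row is a list, each tick is the centre of a partner bin and the vertical line is the MYC bin. All K562 ticks lie at higher coordinates than MYC, and between 30 and 50 of the HCT116 ticks per list do.

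CCND1 had 0 interactions in both full K562 lists, 18 and 25 in HepG2, 41 and 44 in A549 and 54, 52 and 60 in HCT116, all at lower coordinates except 4, 1 and 1 in HCT116. The highest-scoring partner in both HepG2 lists was 520 kb away (chromosome 11, 69120001 to 69130000). EGFR, a receptor kinase gene, had 0 in K562 and HepG2, 20 and 24 in A549 and 35, 32 and 36 in HCT116, where 12 partner bins were in all HCT116 lists and in no other line. MYB had 8 in both K562 lists, 5, 4 and 3 in HCT116 and 0 in HepG2 and A549. Its highest-scoring partner in both K562 lists (chromosome 6, 135430001 to 135440000) lay 250 kb away, within the span of AHI1. CDK6 had 2 in both K562 lists, 9 and 11 in HepG2, 26 and 25 in A549 and 30, 24 and 25 in HCT116. The apoptosis regulator gene BCL2L1 had between 6 and 14 in every list, with 2 partner bins common to all (chromosome 20, 31650001 to 31670000). At equal length BCL2L1 was higher in K562 (0.89 ± 0.24) and HepG2 (1.03 ± 0.24) and lower in HCT116 (-1.40 ± 0.21). The K562 call of BCL2L1 ended without K562 replicate 2 (0.54, adjusted p = 0.132), and the HepG2 call without HepG2 replicate 1 (adjusted p = 0.0537) or 2 (0.0533).

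The genes around CDKN2A were counted because this stretch of chromosome 9 is lost in many cancer lines. CDKN2A, which encodes inhibitors of cell cycle kinases (21990001 to 22000000), had 16, 23 and 16 interactions in the full HCT116 lists and 0 in the other lines. CDKN2B had 10, 23 and 14 in HCT116, 2 in HepG2 replicate 1 and 0 elsewhere. MTAP, a neighbouring metabolic gene (21800001 to 21810000), had 30 and 45 in A549, 38, 31 and 34 in HCT116 and 0 in K562 and HepG2, and DMRTA1 had 7 and 8 in A549 and 0 elsewhere. At equal length MTAP, the only one of the 4 that passed the filter, was higher in A549 (1.68) and HCT116 (0.72) and lower in K562 (-1.20) and HepG2 (-1.20).

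**Figure D4:**
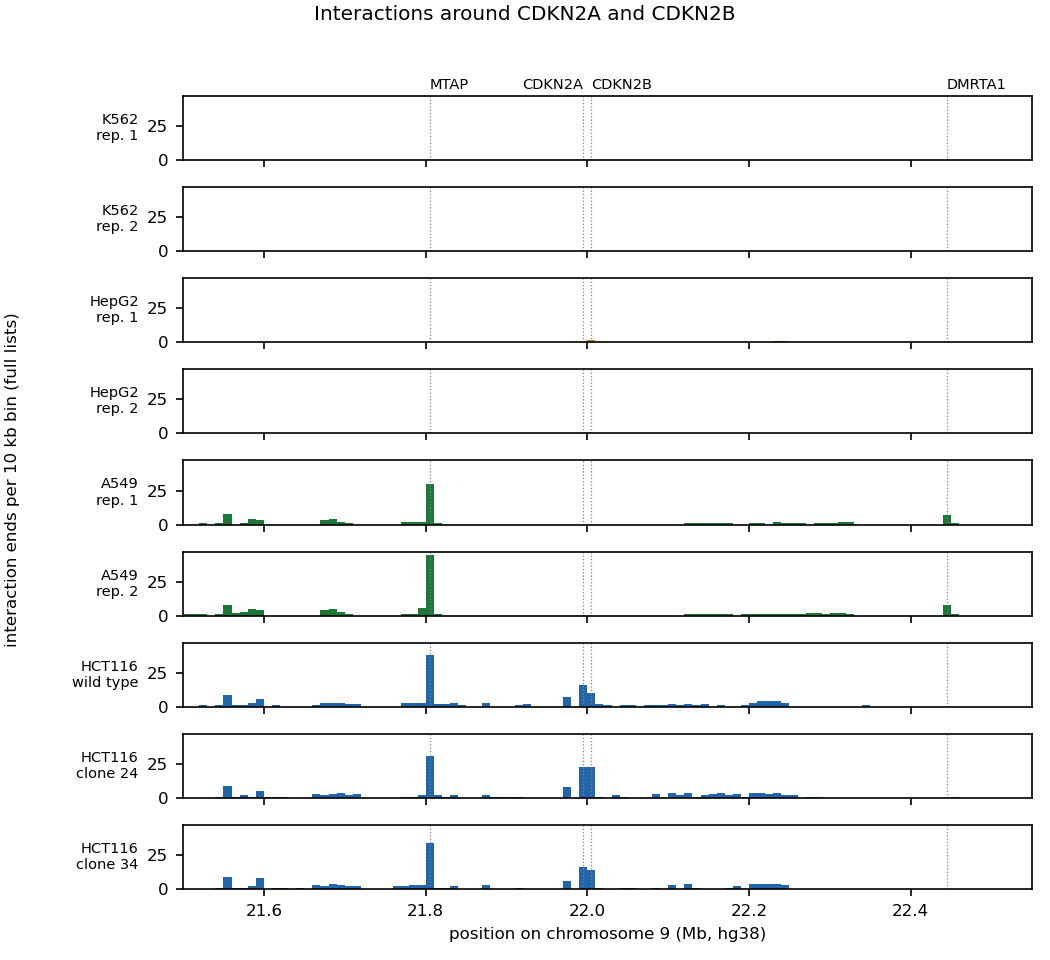
Interaction ends per 10 kb bin around CDKN2A on chromosome 9 (position in Mb, hg38) in the 9 full lists, 1 panel per list, with gene bins as dotted lines. The vertical axis counts ends. A549 has 30 and 45 interactions at MTAP and 0 at CDKN2A, and the HCT116 lists have between 16 and 23 at CDKN2A.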

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

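The tests with both boundary bins, any bin of the gene span, an added constant of 0.5, quantile normalization, other tie orders and a spread no smaller than the counting error were chosen only after the data were seen, as were the filters for gene lists. Of 3517 values of the 184 gene bins past the threshold that the rule for named genes takes under other settings, 3258 kept direction and call, 249 lost the call and 10 reversed. Of the calls lost, 115 were lost with the counting error, under which 69 of the 184 kept the call. Of 728 values of 35 gene lists, the lists named for a line's own tissue apart, 624 kept both, 79 lost the call and 25 reversed, 7 of the 25 with full lists, whose shift of all bins is not taken off in this count. Unless said otherwise, the cause of a change was not tested.

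Of gene bins past the threshold, main counts were 660 in K562, 591 in HepG2, 559 in A549, 546 in HCT116 and 3 in the clones. In that order they were 1538, 1353, 1338, 1585 and 110 with no filter, where more bins are tested, and 354, 339, 308, 287 and 0 with at least 5 interactions in 2 lists, where fewer are (23 clone bins had an unadjusted p under 0.05 in limma). Any bin of the gene span gave 1308, 1141, 1120, 983 and 0 (67 unadjusted for the clones). Merged neighbouring interactions gave 344, 281 and 250 in the first 3 and 20 in the clones. The counting error gave 181, 113, 97, 0 (273 unadjusted) and 0 (0 unadjusted), and HCT116 wild type only gave 193 for HCT116. For the clones, full lists gave 0 (5 unadjusted), both boundary bins 1, an added constant of 0.5 gave 6, quantile normalization 6 and other tie orders a mean of 18.6. With full lists, the median over all bins moved from -0.27 to 0.49 in K562, from -0.14 to 0.33 in HepG2, from 0.04 to -0.36 in A549 and from -0.08 to -0.56 in HCT116, and with quantile normalization to -0.16 in K562. Directions with full lists are read against these shifts.

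With lists left out in turn, the counts ran from 467 to 616 in K562, from 418 upwards in HepG2, 315 (without A549 replicate 2; 321 without replicate 1) to 513 in A549, 394 to 490 in HCT116 and 1 (without HepG2 replicate 1) to 26 (without clone 34; 17 without clone 24) in the clones, where the remaining list of a group was assumed to vary like the others. The overlap difference ran from 0.255 to 0.282, the distance difference from 91.7 to 107 kb, the share of interactions with genes at both ends from -1.56 to -0.957 points (-1.37 without A549 replicate 2, exact permutation p between lines = 0.0429), and the interactions in all lists from 93.45 to 115.85. Medians ran from 0.17 (without K562 replicate 1) to 2.00 for erythroid genes in K562, 2.25 to 2.45 for hepatocyte genes in HepG2, 2.19 to 2.32 for lung genes in A549, -1.22 to -0.34 for mesenchymal genes in K562, -0.86 to 0.78 for erythroid and -0.76 to 0.65 for NRF2 genes in HepG2, -0.45 to 1.69 for hepatocyte genes in A549, and -0.67 to 0.23 for erythroid and -0.78 to 0.12 for mesenchymal genes in HCT116.

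The distance difference was -18.3 kb at equal length. The share of interactions with genes at both ends differed by 2.51 points at equal length, -0.848 with a score of at least 4 and -3.12 when merged. Interactions in all lists numbered 462.4 with bins allowed to differ by 1 and 712 in full lists, where more are compared. With an estimated correlation, erythroid genes in K562 (1.53), hepatocyte genes in HepG2 (2.35) and lung genes in A549 (2.27) each had an adjusted p = 0.287. With full lists, medians were 0.040 for mesenchymal genes in K562, 0.37, 1.44 and 0.18 for growth, NRF2 and ribosomal genes in HepG2, -0.068 and -0.61 for haematopoietic and NRF2 genes in A549 and -0.58 for ribosomal genes in HCT116. RPL30 was then 0.18 in HepG2 and -0.58 in HCT116, UGDH -0.11 in A549 and 0.0021 in HCT116, MYC 0.37 in HepG2 and -0.59 in A549, and CCND1 -0.083 in HCT116. Merged interactions gave -0.61 for epithelial genes in A549, and for MYC -0.36 in K562 and 0.22 in HepG2. MYC in A549 was -0.070 with quantile normalization. NRF2 genes in HepG2 were at 0.72 with at least 5 interactions, p53 targets in HepG2 at -0.22 with no filter (test up), and haematopoietic genes in A549 at -0.19 with no filter and -0.33 with the gene span. Further list calls ended in K562 with full lists (NRF2, adjusted p = 0.0552), in HepG2 with at least 5 interactions or the gene span (growth, 0.268 and 0.201) and with merged interactions, both boundary bins or other tie orders (NRF2, 0.461, 0.0630 and 0.0700). They ended in A549 with at least 5 interactions, HCT116 wild type only or other tie orders (haematopoietic, 0.725, 0.0775 and 0.0595). The hepatocyte call in A549 ended with at least 5 interactions, both boundary bins or quantile normalization (0.358, 0.0556 and 0.0643). The p53 call in A549 ended with no filter (0.736) or the gene span (0.05004), and the NRF2 call in K562 with no filter (0.511). In HCT116 the lung call ended with merged interactions or other tie orders (0.846 and 0.479). Medians that moved by over 1.5 times without 1 list and are not given elsewhere were, in K562, -0.49 for HOX genes (without K562 replicate 1) and -0.65 for mesenchymal genes (K562 replicate 2); in HepG2, 0.99 for WNT targets (HepG2 replicate 2), -0.29 for erythroid genes (HepG2 replicate 1), -1.14 for p53 targets (K562 replicate 1) and -0.25 for NRF2 targets and -0.073 for growth genes (HepG2 replicate 2); in A549, 0.43 and 0.42 for epithelial genes (A549 replicates 1 and 2) and 0.54 for NRF2 targets (A549 replicate 2). In HCT116 they were 1.36 for HOX genes (either A549 list; 1.21 without clone 24), -0.52 for WNT targets (A549 replicate 1), -1.85 and -1.92 for lung genes (A549 replicates 1 and 2), and 0.12, -0.12 and -0.47 for mesenchymal genes (K562 replicates 1 and 2 and HepG2 replicate 2). Replicate numbers did not pair the lists: deviations of 2 lines under the same number correlated across gene bins with r of -0.0628, 0.00727 and 0.0401. TMM factors, DESeq2, read sums, ranking by observed over expected counts and annotated start sites were not run, since the files hold no read counts and the gene table no strand. Depth is unknown, so it cannot be said how many missing interactions it accounts for.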

Other observations

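The tests of correlation along chromosomes, of the subtraction over all higher bins, of the DNA around the clone 24 loci and of other groupings of the lists were chosen only after the results were seen. Windows of 10 Mb, with each interaction counted at its middle, were ranked by how far a line's equal-length lists lay above all others. In K562, chromosome 6 from 20 to 30 Mb, with the histone gene cluster, had a mean of 232 interactions and at most 62 in any other list, and chromosome 22 from 10 to 20 Mb had 67 and at most 23.4. In HepG2, chromosome 14 from 30 to 40 Mb, where FOXA1 lies, had 109.5 and at most 29, and chromosome 20 from 40 to 50 Mb had 93 and at most 27. In A549, chromosome 5 from 50 to 60 Mb, with PLK2, had 57.9 and at most 22, and in HCT116 chromosome 19 from 0 to 10 Mb had 129 and at most 59.

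Among the full HCT116 lists, some genes differed between the clones, by a rule chosen after the values were seen: the list named and both others differed at least 4-fold, with at least 20 interactions in the higher. Clone 24 was low at PLPP3 (4, with 65 in the wild type and 60 in clone 34), TRIB2 (5, with 53 and 45), BHLHE41 with SSPN (2, with 37 and 23), MECOM (4, with 29 and 37) and SEMA6A (4, with 22 and 22). The wild type was high at the growth factor gene FGF9 (24, with 0 in clone 24 and 2 in clone 34) and at RGMB (20, with 0 and 3). Clone 34 had none. These counts have 1 list per clone and no test.

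Higher gene bins of a line lay near each other on chromosomes, and gain or loss of DNA, which is common in cancer lines, is a candidate explanation. Across 908 gene bins, which are not independent replicates, the log2 difference correlated with the mean of bins 2 to 10 Mb away with r of 0.257 in K562, 0.289 in HepG2 and 0.296 in A549, above the highest of 1000 permutations (0.141, 0.148 and 0.176). In HCT116 r was 0.156, with a highest of 0.179, and 1 of 1000 permutations reached it. A regional bias as the whole cause predicts a large fall of the higher bins after subtraction of the neighbours. For bins whose lists lie apart from all others, the median was then 1.58 in K562 (163 bins, 1.77 before), 1.48 in HepG2 (149, 1.83), 1.48 in A549 (151, 1.80) and 1.47 in HCT116 (90, 1.58). Over all higher bins it was 1.33 (234, 1.48), 1.20 (247, 1.44), 1.29 (255, 1.49) and 1.18 (213, 1.16). The predicted fall was not seen, but this cannot decide the question. The bins were picked for their own difference, which neighbours share only weakly, and bins 2 to 10 Mb away miss narrower gains or losses. A regional bias as a part or the whole of the cause stays open in each line, since no copy number was measured. No biological explanation was tested.

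Both A549 lists held no interaction end on chromosome 9 between 21820000 and 22120001, which covers CDKN2A and CDKN2B. A shorter list is argued against, since HCT116 lists kept at least 24 interactions there at the length of A549 replicate 2 and at least 15 at that of replicate 1. Loss of the DNA between the flanks may be the cause: it predicts more interactions across the gap, and A549 had 18 and 21 where HCT116 had 12, 12 and 8. In K562, which had none from 20 to 23 Mb, loss and list length cannot be told apart, since at the length of K562 replicate 2 the HCT116 lists kept as few as 4.22 and both HepG2 lists 2, though the A549 lists kept 16 and 23. Other biological explanations were not tested.

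For the 5 loci low in clone 24, a shorter list is argued against, since the other HCT116 lists at the length of the clone 24 list kept at least 17 interactions at each. Loss of the surrounding DNA could explain them, but at BHLHE41 with SSPN, MECOM and SEMA6A the other interactions within 1 Mb stood at 0.659 or more of the mean of the other HCT116 lists. At PLPP3 and TRIB2 at most 5 such interactions were listed, too few, so loss of DNA there cannot be told apart from a local change. A local change that arose in the clone, or its KRAB-dCas9, was not tested.

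Of the 84 groupings of the 9 lists into 3 and 6, only 1, HCT116 against the rest, gave as many as its 63 gene bins past the threshold in a fit of these 2 groups, and the highest of the others was 9. Every other grouping parts the lists of at least 1 line, so this shows only that the HCT116 lists resemble each other more than the other lists, and 0 HCT116 bins passed with the counting error.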
